A study of Homo sapiens with 9 samples.

How the data were processed

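The series holds 9 RNA sequencing libraries from PC3, a human prostate adenocarcinoma cell line, carrying a luciferase reporter. Per the labels, 3 libraries came from control cells, 3 from a line called GPRC5A knockout 1 and 3 from a line called GPRC5A knockout 2. The labels give replicate numbers but do not state that the replicates came from separate cultures, so the p-values measure the spread between libraries, which may be technical. The way the knockouts were made is not given in the sources used here. Per the labels' protocols, RNA with an integrity number above a set minimum was made into libraries with a stranded mRNA kit, and the series text names an Illumina MiSeq sequencer.

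Per the submitters' processing notes, the tools were TopHat2 2.0.22, featureCounts 1.4.6 and edgeR 3.20.1, and the genome build was hg38. The gene annotation and the strand setting of the read counting were not given in the sources used here. Reads of overlapping and antisense genes therefore cannot be told apart with certainty, and genes with near-identical copies (HLA, IFITM, histone, metallothionein and ribosomal protein genes) are reported as uncertain. The deposited table holds, per the file headers, 26485 genes with chromosome, start, end, strand and length. Its values are a normalised signal, read counts that the authors divided by 1 TMM-type factor per library. All values of each library, 100% of them, were whole multiples of the value of 1 read within a tolerance of 0.01, so the whole read counts were recovered. The deposited table also gives the authors' means, p-values and q-values for 6 knockout against 3 control libraries. The deposited fold change column contains text entries and was not used. Gene length, another column named per the file headers, was not used in any test.

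The libraries held 1975218 to 2360859 recovered reads (1.2-fold range), and a count of 0 allows up to 3 reads, which is 1.23 to 1.61 RPM depending on the library. These floors cover counting error only, because no molecular identifiers are named in the labels and reads are therefore not independent molecules. All deposited values were divided by a common 2.164 to give RPM on the authors' scale, and tests used log2(RPM + 1). Fold changes on this scale understate the change of genes with few reads. Genes at 1 RPM or more in at least 3 of the 9 libraries were tested, which left 14041 genes. No mitochondrially encoded gene of the remaining list was found among the symbols of the table, so that list was not analysed here.

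The main test was limma 3.58.1 in R 4.3.3 with trend and robust moderation, in 1 fit of 3 group means over the 9 libraries, with two-sided p-values adjusted by Benjamini-Hochberg and a threshold of 0.05. The 5 results were knockout 1 against control, knockout 2 against control, genes called the same way in both, the mean of both lines against control, and knockout 2 against knockout 1. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 33 lists with measured members out of 34 fixed. The lists, the tests and the rule for named genes were set before the data were examined. The rule took GPRC5A, the 10 genes that rose and the 10 that fell most in both lines (ranked by the smaller change, at 5 RPM or more in the higher group), the 6 highest and 6 lowest in knockout 2 against knockout 1, and up to 4 examples per list. Other genes named in the text were chosen after their values were seen and are marked as such. The results of 1 list and of some genes that the rule took are not reported here.

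Counts were simulated with 200 changed genes, all drawn from genes at 5 RPM or more in control (13724 genes tested, 5 simulations). Genes at lower levels were tested, but none was simulated as changed. In a simulated knockout 1 comparison the fit recovered 23.0%, 74.0% and 95.2% of genes changed 1.5-fold, 2-fold and 4-fold. In a simulated knockout 2 comparison it recovered 23.6%, 74.6% and 96.1%. For the simulated mean of both lines it recovered 35.2%, 82.4% and 98.2%. Of the simulated calls, 6.31%, 7.45% and 7.83% were false in these 3 comparisons, more than the threshold of 0.05 aims at.

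Alternatives were other pseudocounts and filters, median-of-ratios scaling, limma without trend and robust moderation, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, a minimum fold change, a replicate block, an estimated correlation or fry for the lists, and leaving out each library in turn. Leaving out replicate 3 of both knockout lines together was added after seeing the data, as were edgeR and DESeq2 for GPRC5A, a replicate block in the 2 knockout lines alone and the windows of neighbouring genes. The labels do not say what the replicate numbers share. Correlations of deviations from the group means were 0.152, 0.321 and 0.495 for the same-number libraries of knockout 1 and knockout 2, all above 0.1, so by the rule used the numbers pair these 2 lines. Numbers 1 and 2 were not told apart, since knockout 1 replicate 1 correlated at 0.371 with knockout 2 replicate 2, and knockout 1 replicate 2 at 0.261 with knockout 2 replicate 1, so the block rests mainly on replicate 3. They did not pair control with either line (-0.015 to 0.065 for knockout 1, and 0.005 to 0.202 for knockout 2). GC content was taken from the longest reference transcript of each gene. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.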

Results

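Messenger RNA was sequenced from PC3 cells, an epithelial-like line derived from a prostate adenocarcinoma, to compare control cells with 2 lines labelled as knockouts of the gene GPRC5A. GPRC5A encodes an orphan G protein-coupled receptor whose transcription responds to retinoic acid, and the series title names cell proliferation and bone metastasis as the processes of interest. There were 9 libraries, 3 per group, with between 1975218 and 2360859 reads and between 15199 and 15822 genes with at least 1 read. Levels are given in RPM (reads scaled to library size) on the authors' scale, as mean ± SD with n = 3. Libraries 1 and 2 of knockout 1 differed little beyond counting noise (chi-square per degree of freedom 1.21), as did the control libraries (1.18 to 1.52). Replicate 3 of each knockout line stood apart from its mates, at 10.3 and 10.4 in knockout 1 and at 6.13 and 5.52 in knockout 2, where libraries 1 and 2 gave 2.54.

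GPRC5A transcripts were measured first, because they check the labels. The gene lies on hg38 chromosome 12 from 12891022 to 12913666, on the plus strand, with 4 annotated exons. The control libraries had 19.4, 24.2 and 18.9 RPM, the knockout 1 libraries 7.76, 8.21 and 9.60, and the libraries labelled knockout 2 had 19.1, 16.8 and 16.3. GPRC5A fell from 20.8 ± 2.95 to 8.52 ± 0.958 in knockout 1 (log2 fold change -1.19, SE 0.203, adjusted p = 7.08e-04). In the line labelled knockout 2 the level was 17.4 ± 1.47 (log2 fold change -0.24, SE 0.203, adjusted p = 0.365). The difference between the lines itself passed the test (0.95, adjusted p = 0.00216). Reads were not summed by exon, and an edit that disrupts the protein can leave the transcript in place, so the transcript level does not check the label of the second line. Both measured relatives changed in both lines. GPRC5B rose from 14.4 ± 1.80 to 48.6 ± 8.65 in knockout 1 and to 38.9 ± 10.4 in the line labelled knockout 2 (log2 fold changes 1.68 and 1.35), while GPRC5C fell from 363.5 ± 22.02 to 215.6 ± 36.95 and 115.4 ± 14.1 (-0.76 and -1.65). GPRC5D was under the filter on low values. The 3 measured members of this family list did not pass the list test in knockout 1 (camera adjusted p = 0.503) or knockout 2 (0.653).

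**Figure D1:**
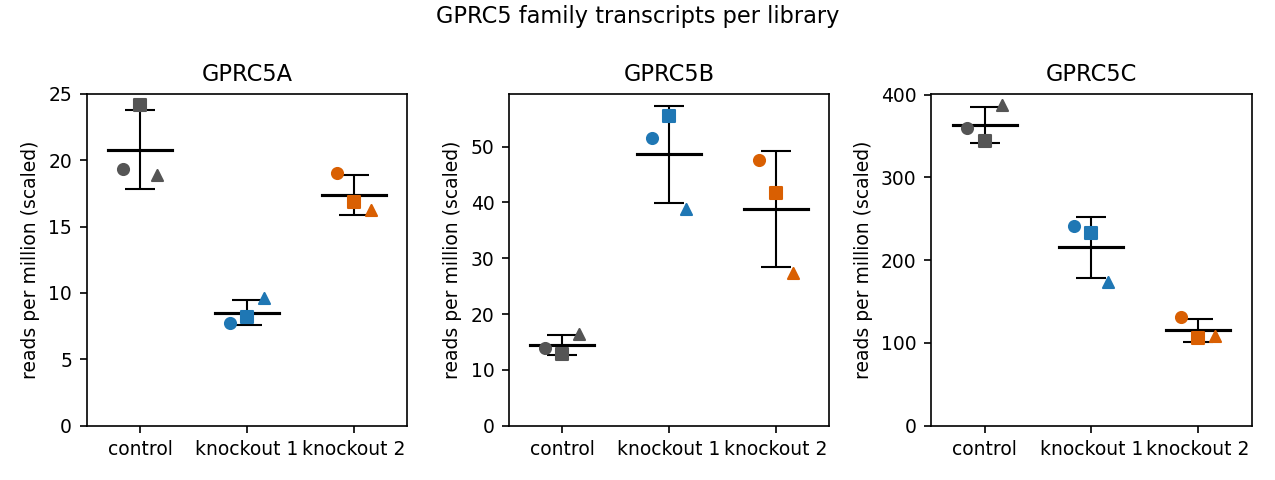
RPM of GPRC5A, GPRC5B and GPRC5C (vertical axes, each from 0) in the 3 control, knockout 1 and knockout 2 libraries, 1 point per library, with bars for the mean and SD. GPRC5A averaged 20.8 in control, 8.52 in knockout 1 and 17.4 in the line labelled knockout 2.

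The comparison of knockout 1 with control asked which transcripts differed in the line whose GPRC5A level was lowered. Interferon-stimulated genes and genes of the cell division cycle were higher, and ribosomal protein and cholesterol synthesis genes were lower. The antiviral gene OAS1 rose from 51.6 ± 11.1 to 279.3 ± 19.99 (log2 fold change 2.43) and MX2 from 5.69 ± 2.18 to 65.9 ± 8.10 (3.38). The mitotic kinase CDK1 rose from 7.34 ± 1.12 to 72.0 ± 53.2 (2.91, SD set mostly by replicate 3), and ITGA1, the collagen-binding integrin alpha-1 chain, fell from 138.4 ± 2.23 to 5.28 ± 2.12 (-4.52). In total 2413 of 14041 genes were called, 1133 higher and 1280 lower, and 945 of them changed at least 2-fold.

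Of the 30 interferon response genes, 28 rose in knockout 1 and 1 fell, both overall and adjusted over the list alone, with a median log2 fold change of 1.79. IFI6 (log2 fold change 2.40) and IFITM1 (2.33), which has close paralogs, were further examples. The member that fell was IRF7 (-0.69, adjusted p = 0.0271), named after its value was seen, and this call was lost without control replicate 1, control replicate 3 or knockout 1 replicate 1, where no member fell. Antigen presentation genes followed the same direction, with 8 of 13 rising (10 adjusted over the list alone) and a median of 0.76. Among them NLRC5, a transactivator of class I genes, had a log2 fold change of 1.39, TAP1, a subunit of the peptide transporter, 0.78 and HLA-C, which has near-identical relatives, 0.84. Camera called both lists (adjusted p = 5.17e-25 and 1.81e-06), and neither call held with an estimated correlation (adjusted p = 0.181 and 0.270 with an estimated correlation).

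Of 30 G2/M and mitosis genes, 26 rose in knockout 1 (29 adjusted over the list alone) and the other 4 did not pass, with a median log2 fold change of 2.31. CENPA, the centromeric histone variant, rose by 2.5, CENPE by 2.40 and CCNB2 by 2.53. Of 28 G1/S and DNA replication genes, 15 rose (22 adjusted over the list alone), with a median of 1.30, and among them MCM5, a helicase subunit, rose by 1.35 and the transcription factor E2F1 by 1.41. Knockout 1 replicate 3 stood apart in both lists. Its G2/M median lay 3.46 above the control mean, against 1.77 and 1.72 in replicates 1 and 2, and its G1/S median 1.92 above, against 0.90 and 0.83. Camera called both lists (adjusted p = 4.81e-20 and 3.44e-12), with adjusted p = 0.334 and 0.414 with an estimated correlation. Without replicate 3 of both knockout lines, an alternative chosen after seeing the data, 29 G2/M genes and 19 G1/S genes rose and 1 G2/M gene fell, with medians of 1.70 and 0.93, and the p-values with an estimated correlation became 0.0336 and 0.0336.

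The lists that fell in knockout 1 concerned translation, sterol synthesis, adhesion, protein folding and respiration. Of 30 cytosolic ribosomal protein genes, 29 fell (30 adjusted over the list alone), with a median log2 fold change of -0.77, including RPL32 (-1.35), RPS23 (-1.15) and RPL37 (-1.02), many of which have processed pseudogenes. This was the list whose call held with an estimated correlation (adjusted p = 2.49e-26 with the preset and 0.0177 with an estimated correlation), and its library medians were -0.73, -0.76 and -0.74, so replicate 3 did not stand apart. Of 21 cholesterol synthesis genes, 10 fell (19 adjusted over the list alone), with a median of -0.48, including DHCR7, the last enzyme of the pathway (-0.93), and the cyclase LSS (-0.64). Of 24 integrin, laminin and matrix protease genes, 7 fell in both counts and 0 rose (1 adjusted over the list alone), with a list median of -0.22. Those that fell included ITGA2 (-2.59) and the collagenase MMP1 (-1.63). Without replicate 3 of both knockout lines 13 of these genes fell and 4 rose. Camera called these lists at adjusted p = 2.38e-09 and 0.00740, with adjusted p = 0.181 and 0.284 with an estimated correlation.

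Of 20 genes of the unfolded protein and amino acid stress response, 5 fell in knockout 1 in both counts, with a median of -0.56. Serine synthesis enzyme PHGDH (-0.78) and the endoplasmic reticulum protein SDF2L1 (-0.94) were among them, and the count was 3 without control replicate 2 or control replicate 3. Here too replicate 3 stood apart, at -1.27 against -0.22 and -0.32 for replicates 1 and 2. Without replicate 3 of both knockout lines 10 members fell and the list median was -0.29. Camera called the list (adjusted p = 4.33e-06, and adjusted p = 0.531 with an estimated correlation). Of 28 nuclear-encoded oxidative phosphorylation genes, 6 fell (7 adjusted over the list alone) and 2 rose, with a median of -0.22, and SDHA, the flavoprotein of complex II, fell by 0.95. Replicate 3 had a median of 0.12 here, against -0.32 and -0.46 in replicates 1 and 2. The camera call (adjusted p = 0.0460, and adjusted p = 0.713 with an estimated correlation) was lost without control replicate 2 (0.0792), control replicate 3 (0.0524), knockout 1 replicate 1 (0.313) or knockout 1 replicate 2 (0.381). The number of members that fell was 3 without control replicate 1, 2 without any of those 4 libraries, and 12 without knockout 1 replicate 3.

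In all, camera called 9 of 33 lists in knockout 1, of which 1 held with an estimated correlation. The count of 2413 called genes fell to 1430, 1556 and 1460 when control replicates 1, 2 and 3 were left out in turn, and it was 3742 without replicate 3 of both knockout lines, of which 2286 were among the 2413.

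The comparison of the line labelled knockout 2 with control asked the same question of a line in which the GPRC5A transcript was not measurably lower. Cell division genes were higher as in the first line, but interferon and antigen presentation genes were lower, and epithelial junction genes were much lower. The desmosomal plakin DSP fell from 167.4 ± 5.78 to 1.06 ± 0.727 (log2 fold change -6.41), and the simple epithelial keratin KRT8 fell from 362.3 ± 20.3 to 88.1 ± 12.2 (-2.04). AKAP12, a scaffold for protein kinase A, rose from 154.5 ± 13.3 to 1879 ± 331.6 (3.58), and FBLN1, which encodes the matrix protein fibulin-1, from 5.29 ± 2.31 to 68.7 ± 7.79 (3.52). In total 5781 genes were called, 2755 higher and 3026 lower, and 2460 of them changed at least 2-fold.

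Of 19 epithelial junction and keratin genes, 13 fell and 2 rose in knockout 2, overall and adjusted over the list alone, with a median log2 fold change of -1.32. Those that fell included CLDN4, a tight junction claudin (-1.23), the desmosomal PKP3 (-1.04) and, named after their values were seen, EPCAM (-3.85) and CDH1, which encodes E-cadherin (-3.16). The members that rose, also named afterwards, were CLDN1 (1.15) and the junction scaffold TJP1 (0.88). The camera call held with an estimated correlation (adjusted p = 1.62e-06 with the preset and 0.0475 with an estimated correlation), but without replicate 3 of both lines the value with an estimated correlation was 0.0538. The library medians were -1.20, -1.32 and -1.56. In knockout 1, 4 of these genes fell and 3 rose (7 and 3 adjusted over the list alone), with a median of -0.27 and camera adjusted p = 0.517. The 3 became 1 without control replicate 1.

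Fibroblast and stromal markers rose in knockout 2, 6 of 8 with 1 falling in both counts, with a median of 1.73, or 1.44 with LUM (named after its value was seen), at 0 reads in control, set to its bound. COL3A1, a fibrillar collagen (3.35), and MYL9, a myosin light chain (2.11), were among them. Camera called the list (adjusted p = 0.00123), with adjusted p = 0.116 with an estimated correlation. In knockout 1, 3 of these markers rose and 2 fell in both counts (camera adjusted p = 0.713), with a median of 0.25 that became -0.02 with the gene at 0 in one group set to its bound.

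Of 30 interferon response genes, 17 fell in knockout 2 and 13 did not pass, in both counts, with a median of -0.74. OAS1 fell by 2.48, IFI6 by 1.44 and MX2 by 1.5. Of 13 antigen presentation genes, 9 fell in both counts, with a median of -0.66, among them TAP1 (-1.55), PSMB8, an immunoproteasome subunit (-1.06), and NLRC5 (-1.33). Camera called both lists (adjusted p = 1.37e-05 and 2.87e-04), with adjusted p = 0.339 and 0.260 with an estimated correlation.

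Of 30 G2/M and mitosis genes, 29 rose in knockout 2 and 1 fell, in both counts, with a median of 2.71. CDK1 rose from 7.34 ± 1.12 to 84.1 ± 40.3 (3.26) and CENPE rose by 3.27. The member that fell, named afterwards, was the phosphatase gene CDC25B (-0.96). Of 28 G1/S genes, 22 rose (23 adjusted over the list alone), with a median of 1.4, including MCM10 (2.53) and GINS2 (2.19). As in knockout 1, replicate 3 stood apart, with a G2/M median of 3.66 against 2.22 and 2.45, and a G1/S median of 1.85 against 1.31 and 0.98. Camera called both lists (adjusted p = 5.60e-13 and 7.92e-08), with adjusted p = 0.327 and 0.339 with an estimated correlation. Without replicate 3 of both lines 29 and 21 members rose, with medians of 2.33 and 1.18, and the p with an estimated correlation was 0.0538 for each list.

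Of 20 CDK inhibitor and p53 target genes, 8 fell in knockout 2 and 12 did not pass, in both counts. CDKN1A, which encodes the inhibitor p21, fell from 51.9 ± 1.92 to 23.3 ± 3.70 (-1.13) and RRM2B by 0.85. The median was -0.44, or -0.34 with FAS (named after its value was seen), at 0 reads in knockout 2, set to its bound. The camera call (adjusted p = 0.0258, and adjusted p = 0.260 with an estimated correlation) was lost without knockout 2 replicate 3 (0.0516) or replicate 3 of both lines (0.0681), and the 8 became 4 without control replicate 2, 5 without control replicate 3 and 4 without knockout 2 replicate 3. Of 10 measured replication-dependent histone genes, 6 rose and 1 fell in both counts, with a median of 0.56, including the linker histone HIST1H1C (1.77) and HIST1H2BC (1.39). Its camera call (0.0357, and adjusted p = 0.260 with an estimated correlation) was lost without knockout 2 replicate 1 (0.0649). In knockout 1 the CDK inhibitor list had 1 member rising, CDKN2C (0.75), and 19 that did not pass, in both counts (camera adjusted p = 0.426), and 2 histone genes rose (3 adjusted over the list alone, and 1 overall without control replicate 3 or knockout 1 replicate 2; camera adjusted p = 0.327). In knockout 1 the list medians were -0.18 and 0.06.

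Of 22 genes associated with bone metastasis, 10 rose (11 adjusted over the list alone) and 4 fell in knockout 2, with a median of 0.74. The Wnt inhibitor DKK1 rose from 617.7 ± 23.1 to 1997 ± 391.5 (1.67), the matricellular gene CTGF by 1.52 and the collagenase MMP13 by 1.42, while MMP1 fell by 1.17. The camera call (adjusted p = 0.0258, and adjusted p = 0.339 with an estimated correlation) was lost without knockout 2 replicate 1 (0.0561). In knockout 1, 4 members rose and 3 fell (6 and 5 adjusted over the list alone), with a median of 0.29 and camera adjusted p = 0.517. There DKK1 also rose, by 1.24, and CTGF by 2.1, but MMP13 fell by 1.63.

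The remaining lists that fell in knockout 2 covered lipid synthesis, adhesion, Notch signalling, stress, translation and respiration. Of 24 integrin, laminin and matrix protease genes, 14 fell and 3 rose in both counts (median -0.62), with ITGA1 at -4.41 and ITGA2 at -1.74. Of 12 Notch pathway genes, 4 fell and 8 did not pass in both counts (median -0.49), with the Notch effector HEY1 at -3.52 and the ligand JAG1 at -1.35. Of 21 cholesterol synthesis genes, 15 fell (17 adjusted over the list alone) and 1 rose (median -0.54), and the 15 became 9 without control replicate 3. LSS fell by 0.78, whereas STARD4, a sterol carrier, rose by 0.80. Of 14 fatty acid synthesis genes, 6 fell and 2 rose in both counts (median -0.28), with the desaturase FADS2 at -1.47, fatty acid synthase FASN at -1.33 and the elongase ELOVL6 at 1.92. Camera called these lists at adjusted p = 0.00644, 0.0350, 8.65e-05 and 0.0222, with adjusted p = 0.260 for each with an estimated correlation. The Notch call was lost without knockout 2 replicate 2 (0.0599).

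Of 20 unfolded protein and amino acid stress genes, 16 fell in knockout 2 (18 adjusted over the list alone), with a median of -1.02 and with replicate 3 at -1.24 against -0.96 and -0.78. PHGDH fell by 1.4 and PSAT1, another enzyme of serine synthesis, by 1.74, and the 16 became 10 without control replicate 2. Of 30 ribosomal protein genes, 22 fell in both counts (median -0.54), with RPL37 at -1.73 and RPL32 at -1.24. Of 28 oxidative phosphorylation genes, 12 fell and 1 rose in both counts (median -0.40), with SDHA at -1.35 and UQCRB at -0.94. Replicate 3 stood at -0.15 in this list, against -0.55 and -0.44 in replicates 1 and 2. Camera called the 3 lists at adjusted p = 5.05e-06, 2.34e-07 and 0.00644, with adjusted p = 0.375, 0.116 and 0.616 with an estimated correlation. In all, camera called 17 of 33 lists in knockout 2, of which 1 held with an estimated correlation.

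**Figure D2:**
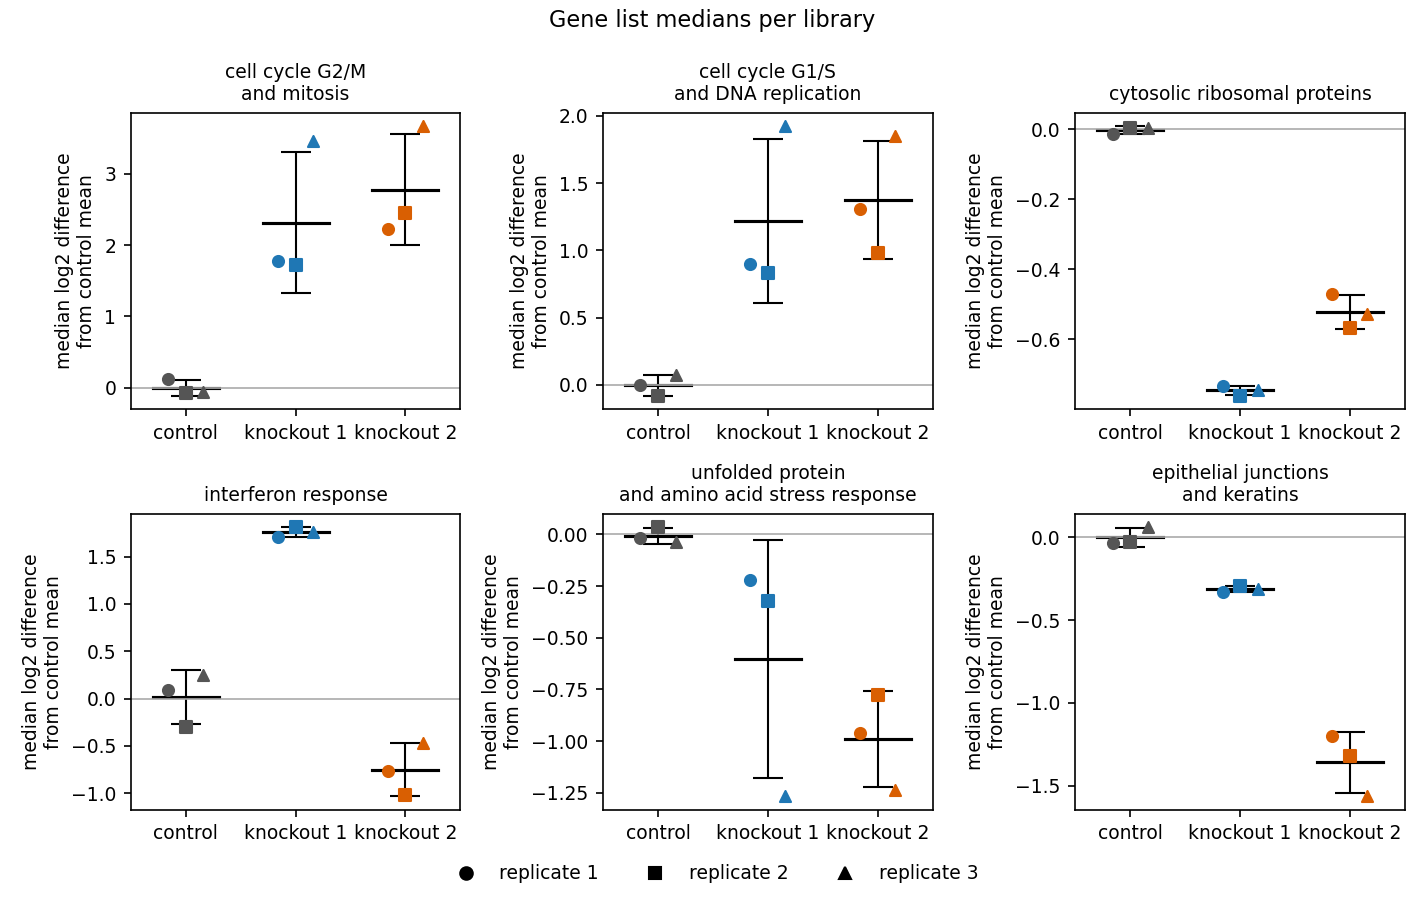
Median log2 difference from the control mean (vertical axes) over the members of 6 gene lists in each library, with control, knockout 1 and knockout 2 side by side, marker shapes for replicates 1 to 3, and bars for the mean and SD of the 3 library medians. Replicate 3 of each knockout line lay highest for the G2/M list, at 3.46 and 3.66, and interferon response genes lay at 1.71 to 1.81 in knockout 1 and -1.02 to -0.46 in knockout 2.

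Genes that changed the same way in both lines were the comparison that the pair of lines implies. MKI67, the proliferation antigen Ki-67, rose from 12.8 ± 2.82 to 181.6 ± 141.1 in knockout 1 and 186.4 ± 111 in knockout 2. TCN1, a secreted vitamin B12 carrier, fell from 87.3 ± 15.5 to 1.20 ± 0.732 and 0.144 ± 0.25. The basement membrane proteoglycan gene HSPG2 fell from 856.9 ± 91.3 to 81.0 ± 12.6 and 38.7 ± 7.18.

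By the rule fixed beforehand, the 10 genes that rose most in both lines were MYBL2, MKI67, KIF20A, DLGAP5, RRM2, ANLN, GTSE1, IQGAP3, PBK and CDH6. Most of these have known roles in DNA synthesis, spindle function or cytokinesis, and in all but CDH6 replicate 3 lay higher than replicates 1 and 2 in both lines. MYBL2, on chromosome 20 from 43667019, had log2 fold changes of 3.87 and 4.16 (adjusted p = 0.00513 and 0.00133). The cadherin CDH6, on chromosome 5 from 31193655, rose from 1.5 ± 0.880 to 56.8 ± 21.9 and 18.3 ± 0.663 (4.52 and 3.02, adjusted p = 1.49e-07 and 2.33e-06). Those that fell most included TCN1, FAM110C, ITGA1, GABRA3, WDR72, TLR4, CSMD2, HSPG2 and TFF2. ITGA1, on chromosome 5 from 52788302, lost most of its transcript in both lines (-4.52 and -4.41, adjusted p = 1.23e-08 and 1.26e-09). FAM110C, at 70.5 ± 5.4 in control, had 0 reads in knockout 2, where it was at least 52.6-fold lower by the floor of 3 counts per library. GABRA3 had 0 reads in knockout 1, at least 16.5-fold lower, and the toll-like receptor gene TLR4 and CSMD2 had 0 in knockout 2, at least 10.3-fold and 10.5-fold lower.

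In all, 1552 genes were called the same way in both lines, 706 higher and 846 lower, and 573 of them changed at least 2-fold in each. Independent lists of these sizes would share 222.3 and 275.9 genes in the 2 directions. A further 137 genes were called in opposite directions, where independent lists would share 495.3. Groups simulated with no changed gene, both set against 1 simulated control group, shared 0.04 genes on average over 50 simulations. With no changed gene almost nothing passes the adjusted threshold, so this low count was built in. It does not show how much of the 1552 comes from the shared controls. Log2 fold changes of the 2 lines correlated across genes with r = 0.54, against 0.50 for simulated unchanged groups, and genes are not independent replicates. Their covariance was 0.295 against 0.0377, a difference of 0.257. The 3 control libraries could not be divided into parts of at least 2, so part of the excess may come from the shared controls. The 1552 became 906, 972 and 914 without control replicates 1, 2 and 3. Of the lists, 7 were called in both lines in the same direction and 2, interferon response and antigen presentation, in opposite directions. With an estimated correlation 1 list was called in each line, ribosomal proteins in knockout 1 and epithelial genes in knockout 2, so none was called in both.

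**Figure D3:**
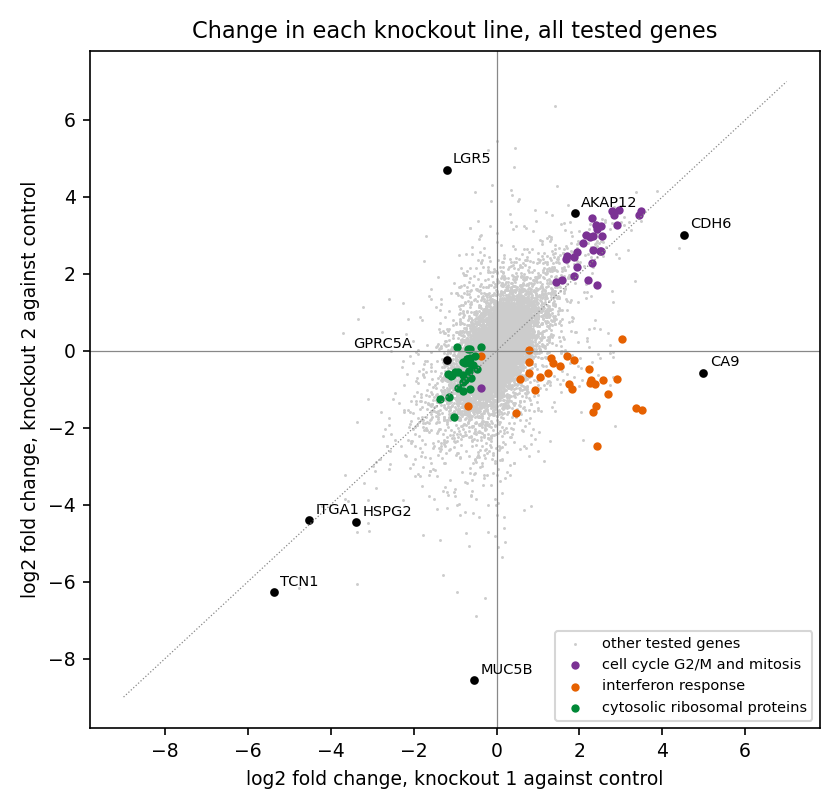
Log2 fold change of each tested gene in knockout 1 (horizontal axis) and knockout 2 (vertical axis) against control, with members of 3 lists coloured, single genes named in black and a dotted line where the lines are equal. G2/M genes lay high in both lines (list medians 2.31 and 2.71), ribosomal protein genes low (-0.77 and -0.54), and interferon genes on opposite sides (1.79 and -0.74).

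The mean of both lines was set against control, which is also what the authors' deposited table compares. Cell division genes were again higher and ribosomal protein and sterol genes lower, while interferon genes, which moved apart in the 2 lines, were mixed. In this contrast 29 of 30 G2/M genes rose and 1 fell (median log2 fold change 2.55), 29 of 30 ribosomal protein genes fell (-0.63), 18 of 21 cholesterol synthesis genes fell (-0.50), and 11 of 30 interferon genes rose and 2 fell (0.50), with the same counts adjusted over each list alone. Camera called 10 of 33 lists, with adjusted p = 1.80e-17, 1.17e-16, 1.18e-07 and 0.00103 for these 4, and none of the 10 held with an estimated correlation (adjusted p = 0.316, 0.0621, 0.202 and 0.489 with an estimated correlation). AKAP12 rose by 2.73 in the mean, TXNRD1, a thioredoxin reductase, by 1.59 and GPRC5B by 1.51, while HSPG2 fell by 3.92. The test called 4544 genes, 2170 higher and 2374 lower. The authors' deposited table marked 1506 genes at q under 0.05, 704 higher and 802 lower in the knockout mean. Of these, 1492 were called here for the mean and 1247 the same way in both lines. The q of GPRC5A in the authors' deposited table was 0.293.

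The 2 knockout lines were then compared directly, which asked how far lines with the same target differ. Interferon response and antigen presentation genes were much lower in knockout 2 than in knockout 1, epithelial genes were lower and stromal genes higher. MUC5B, a secreted mucin on chromosome 11 from 1223065, stood at 468.6 ± 49.7 in control and 333.3 ± 107.6 in knockout 1 but 0.310 ± 0.536 in knockout 2 (log2 difference between the lines -8.01, adjusted p = 1.36e-09). CA9, a hypoxia-inducible carbonic anhydrase, rose in knockout 1 from 2.3 ± 1.5 to 97.4 ± 6.14 and was at 1.35 ± 1.21 in knockout 2 (-5.56). LGR5, a Wnt-associated stem cell receptor on chromosome 12 from 71439770, reached 60.04 ± 12.5 in knockout 2 and had 0 reads in knockout 1 (5.91).

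The 6 genes highest in knockout 2 against knockout 1 were LGR5, CA10, PTPRT, SCN3A, OSTN and ANO3. CA10 had 0 reads in control and in knockout 1 and 42.7 ± 5.70 in knockout 2, at least 28.6-fold higher than control. The voltage-gated sodium channel gene SCN3A stood at 107.2 ± 11.1 in knockout 2 against 0.333 ± 0.291 in control (6.36). The 6 lowest were MUC5B, LCP1, DSP, CA9, SLFN11 and MID1IP1. The actin-bundling gene LCP1 stood at 96.7 ± 16.8 in knockout 1 and 0.155 ± 0.268 in knockout 2 (-6.41), and SLFN11, which acts in the response to replication stress, at 50.4 ± 11.2 and 0.148 ± 0.256 (-5.48).

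Between the lines 29 of 30 interferon genes were lower in knockout 2 (median -2.37), and all 13 antigen presentation genes were lower (-1.49). Of 19 epithelial genes 11 were lower (12 adjusted over the list alone) and 1 higher (-1.17), and of 8 stromal markers 5 were higher (6 adjusted over the list alone) and 1 lower (1.71), or 6 and 0 with a replicate block in the 2 knockout lines. Camera called the epithelial list (adjusted p = 1.31e-06 with the preset and 0.0434 with an estimated correlation). With an estimated correlation this call was lost with the block (0.573) or without replicate 3 of both lines (0.140). For the other 3 lists the adjusted p was 2.14e-26, 1.23e-10 and 0.00138, with adjusted p = 0.10 for each with an estimated correlation. For the G2/M list the difference did not pass (median 0.51, camera adjusted p = 0.150), with 1 gene lower and 29 that did not pass in limma. With the block 14 G2/M genes were higher and 2 lower (camera adjusted p = 0.00162, and adjusted p = 0.723 with an estimated correlation). Without knockout 1 replicate 3, 17 G2/M genes were higher in knockout 2 and the median was 1.06. Of 14041 genes, 4173 differed between the lines, 1919 higher and 2254 lower in knockout 2.

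Neighbouring genes were also compared along the chromosomes, in windows of 40 tested genes chosen after the data were seen. Long stretches shifted together in 1 or both lines. On hg38 chromosome 2 from 131.5 to 237.9 Mb, the median log2 fold change of 360 genes was 0.53 in knockout 1 and 0.48 in knockout 2, with 87.5% and 77.5% of them higher than control. On chromosome 3 from 2.1 to 66.4 Mb, 360 genes had medians of -0.45 and -0.47. On chromosome 14 from 24.4 to 57.4 Mb, 120 genes had a median of 0.77 in knockout 2 and 0.04 in knockout 1, and on chromosome 5 from 0.140 to 52.8 Mb, 120 genes had medians of -0.58 and -0.27. The first window of chromosome 9 lay at -0.75 in knockout 1 and 0.74 in knockout 2. In all, 36 of 327 windows in knockout 1 and 43 of 327 in knockout 2 lay beyond the 95% limit of the most extreme window under shuffled gene order (0.32 and 0.48), and 12 lay beyond it in both lines, 11 with the same sign, with both lines compared with the same controls. Medians per library were taken only for long runs of windows beyond the limit, where each library of the line shifted the same way. In the run on chromosome 2 from 131.5 to 237.9 Mb the 6 knockout libraries had medians of 0.38 to 0.56.

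**Figure D4:**
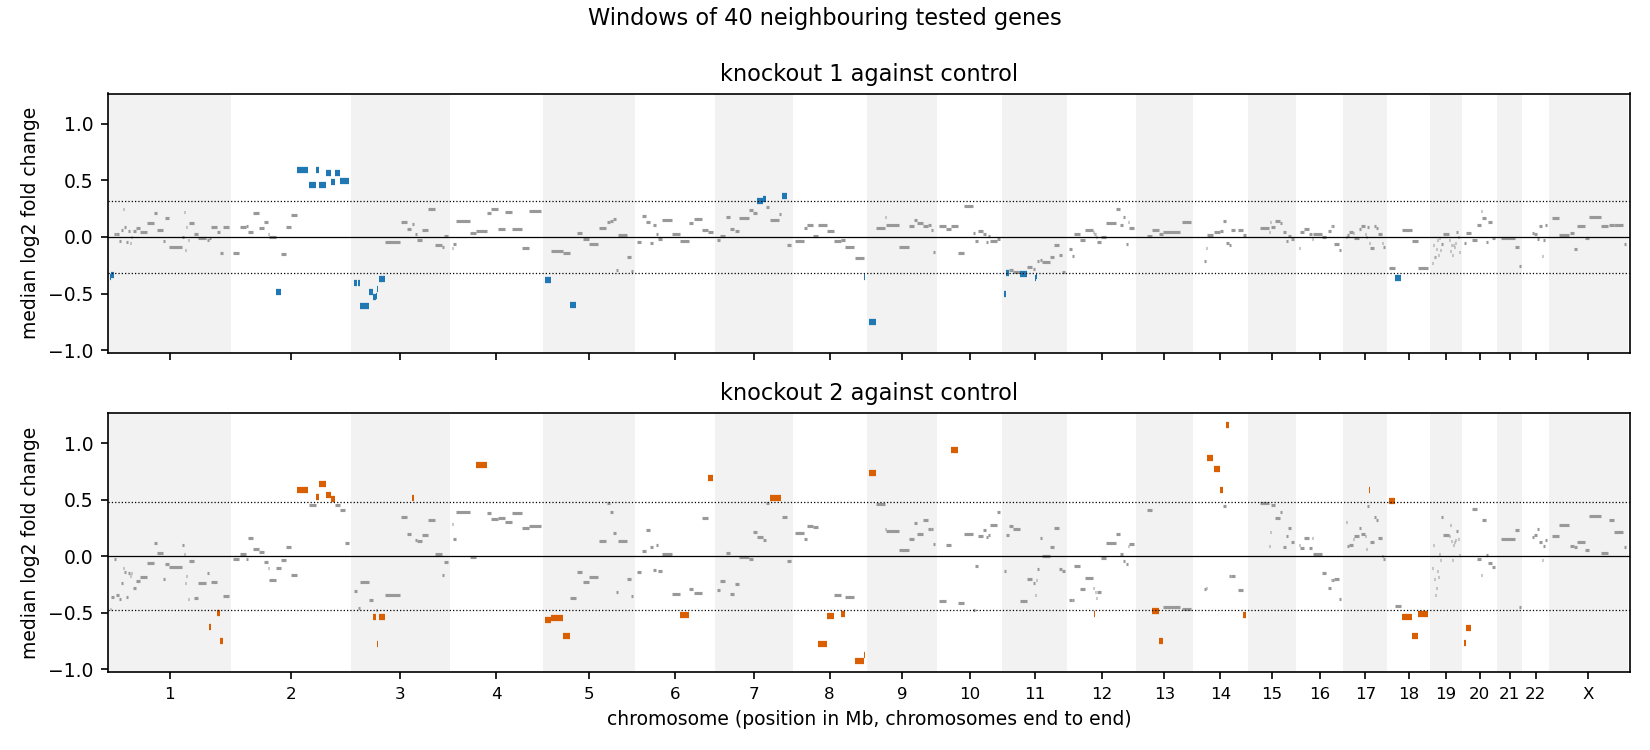
Median log2 fold change against control (vertical axes) in windows of 40 neighbouring tested genes along the chromosomes placed end to end (horizontal axis, Mb), knockout 1 above and knockout 2 under it, with dotted lines at the limits from shuffled gene order (0.32 and 0.48) and coloured windows beyond them. Windows beyond the limit numbered 36 of 327 in knockout 1 and 43 of 327 in knockout 2.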

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

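The test of the difference between the 2 knockout lines was set before the data were examined, and each result here passed it. Of 154 named genes, 83 differed between the lines, 16 of them called in opposite directions against control. Some of the 154 were named for having the highest or lowest values of this same difference, so their passing was built in. The share of named genes that differed therefore does not carry over to other genes. Among all 14041 tested genes, 4173 differed between the lines (29.7%). Values are log2 differences, knockout 2 minus knockout 1, and no explanation was tested for single genes or lists in this part.

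By list, the median difference was -2.37 for interferon response, -1.49 for antigen presentation, -1.17 for epithelial junctions and keratins, -0.35 for fatty acid synthesis and -0.55 for the unfolded protein and amino acid stress response. It was 1.71 for fibroblast and stromal markers and 0.34 for cytosolic ribosomal proteins. For the lists not given in the direct comparison above, 7 of 14 fatty acid genes were lower (camera adjusted p = 0.0470, and adjusted p = 0.338 with an estimated correlation, but 0.0658 by camera with a replicate block in the 2 knockout lines), 4 of 20 stress genes lower and 1 higher (0.0470, and adjusted p = 0.758 with an estimated correlation, with 10 lower under the block), and 16 of 30 ribosomal protein genes higher and 2 lower (0.00185, and adjusted p = 0.281 with an estimated correlation), with the same counts adjusted over each list alone. Without knockout 1 replicate 3, which stood apart, 15 stress genes were lower and the median was -0.78.

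GPRC5A differed by 0.95 and its relative GPRC5C by -0.89. Among the genes that changed most in both lines, the differences were -1.50 for CDH6, -0.91 for TCN1 (call lost with the block, adjusted p = 0.10), -1.38 for FAM110C, -1.05 for HSPG2 and -2.70 for TFF2. The genes with the highest differences were LGR5 (5.91), CA10 (5.44), PTPRT (5.43), SCN3A (4.94), OSTN (4.84) and ANO3 (4.68), and those with the lowest MUC5B (-8.01), LCP1 (-6.41), DSP (-6.14), CA9 (-5.56), SLFN11 (-5.48) and MID1IP1 (-5.30). Several of these had 0 reads in 1 line, where the fitted difference depends on the pseudocount and is no bound.

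Interferon response genes differed by -4.91 (OAS1), -3.84 (IFI6), -3.91 (IFITM1) and -4.87 (MX2), and antigen presentation genes by -2.72 (NLRC5), -1.49 (HLA-C), -2.32 (TAP1) and -1.82 (PSMB8). Inflammatory and STAT3-related genes differed by -3.62 (CCL2), 1.22 (SOCS3) and -0.53 (OSMR). Cell cycle inhibitor and p53 target genes differed by -1.13 (CDKN1A), -0.47 (RRM2B) and -1.03 (CDKN2C), and histone genes, which have close copies, by 0.94 (HIST1H1C), 0.67 (HIST1H2BC) and 0.53 (HIST1H2BD).

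Genes of EGFR and MAPK signalling differed by -2.78 (TGFA), -2.06 (ERBB3), -2.91 (LRIG1) and -1.05 (SPRY2). Genes responsive to cAMP differed by 1.70 (AKAP12), 1.05 (CREM), 1.17 (DUSP1) and -2.01 (PRKAR2B), and those responsive to retinoic acid by 0.84 (CRABP2) and -0.58 (ALDH1A3, call lost with the block, adjusted p = 0.0678). For TGF-beta and YAP/TAZ genes the values were 0.66 (ID2), 1.84 (TGFB2), 1.21 (TGFBR2), -0.87 (NT5E) and 0.62 (CYR61), and for Notch genes -1.72 (HEY1), -1.23 (JAG1) and 1.15 (DLL4).

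Epithelial genes differed by -3.62 (CDH3) and -1.51 (KRT8), and mesenchymal and stromal genes by 2.42 (COL1A1), -0.74 (CDH11), 2.19 (FBLN1) and 1.58 (COL3A1). Genes of bone metastasis and matrix turnover differed by 0.46 (MMP1), -0.58 (CTGF), 0.44 (DKK1), 3.05 (MMP13) and 0.85 (ITGA2). Markers of other cell types differed by -0.55 (ENO2), 2.76 (SCG5), -3.48 (KDR), -2.06 (PECAM1) and 0.99 (CD68).

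Metabolic and stress genes differed by -0.58 (NDRG1), -0.74 (SLC2A1), 1.85 (STARD4), -0.66 (FADS2), -0.72 (SCD), -0.62 (PHGDH), -0.99 (PSAT1) and 1.57 (MT2A, which has close paralogs). The remaining values were -2.17 for the survival gene BCL2, -0.71 for RPL37, -0.38 for COX4I1 and -0.54 for UQCRB.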

How the results depend on the processing

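Leaving out replicate 3 of both knockout lines together, edgeR and DESeq2 for GPRC5A, and a replicate block in the knockout lines alone were chosen after the data were seen, and the other alternatives were set before. Asking for at least a 2-fold change left 945 genes in knockout 1, 2460 in knockout 2, 573 in both, 1388 for the mean and 1607 between the lines, because fewer genes can pass. Leaving out 1 library at a time gave 1430 to 2723 genes in knockout 1, and 906 to 1658 in both. The lowest counts came without a control library. Without control replicates 1, 2 and 3 they were 1430, 1556 and 1460 in knockout 1, and 906, 972 and 914 in both. Without knockout 1 replicates 1, 2 and 3, which also takes 1 library from a compared group, 1898, 1964 and 2690 genes were called in knockout 1. Why control libraries weighed more was not tested. Without replicate 3 of both knockout lines 3742 genes were called in knockout 1, and the cause was not tested. Gene lists called in knockout 1 and knockout 2 numbered 1 and 1 with an estimated correlation, and 15 and 28 with fry, which asks whether a list moves and not whether it moves more than other genes. The ribosomal protein list in knockout 1 and the epithelial list in knockout 2 were the 2 of 26 list results called under every alternative that changed 1 choice. With an estimated correlation as well, their adjusted p was 0.0894 and 0.236 with a replicate block, and 0.0336 and 0.0538 without replicate 3 of both lines. For the other 24 the call was lost with an estimated correlation. With genes at 5 RPM or more, 5 list calls were lost, with adjusted p = 0.0593 for oxidative phosphorylation in knockout 1 and 0.0801, 0.0515, 0.143 and 0.105 for p53 targets, histones, bone metastasis and Notch in knockout 2. With fry 3 were lost, the stress response (0.0844) and oxidative phosphorylation (0.357) in knockout 1 and the latter in knockout 2 (0.0754). Of 284 called results for named genes, 250 kept their direction and call under every alternative that could test them, and no direction reversed. The calls lost numbered 158 over the alternatives, with 19, 25 and 28 of 274 without control replicates 1, 2 and 3, 16 of 284 with limma without trend and robust moderation and 12 with DESeq2. Median-of-ratios scaling shifted the median log2 fold change by 0.009 in each line and lost no named call. Replicate numbers did not pair control with either line (0 of 3 and 1 of 3 pairs above 0.1), and a replicate block over all libraries gave 2936 genes in knockout 1, 6197 in knockout 2 and 1885 in both. The block in the 2 knockout lines, which the numbers pair, gave 4672 genes between them, kept 81 of 83 named calls and called the EGFR list (camera adjusted p = 0.0445, and adjusted p = 0.641 with an estimated correlation). Besides the changes printed beside their results, it changed no other call made between the lines. At 1975218 to 2360859 reads per library, changes of 1.5-fold were mostly missed in simulated data, where changed genes had 5 RPM or more in control. There 23% of such genes were recovered for knockout 1. The simulated data held far fewer changed genes than were called here, so the same adjusted threshold was stricter there. That share therefore does not carry over to these comparisons, where recovery was not measured. A gene not called here may still differ by 1.5-fold. The range of calls without 1 library was 1430 to 2723 in knockout 1.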

Other observations

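The tests of exchanged labels, of the third libraries and of deletion around single genes were chosen after the result was seen, as were the gene windows themselves. Gene lists not yet described did not pass camera in either line, but held genes that changed alike in both. The redox enzymes TXNRD1 (log2 fold changes 1.63 in knockout 1 and 1.55 in knockout 2) and NQO1 (1.26 and 1.07) rose, and in the NRF2 and metal response list 3 genes rose and 3 fell in knockout 1 and 7 rose and 3 fell in knockout 2 (medians 0.26 and 0.31, camera adjusted p = 0.503 and 0.151). Those counts became 6 rising in knockout 1 without knockout 1 replicate 3, 4 rising in knockout 2 without control replicate 2, and 1 falling without control replicate 1 or 3. The chemokine CXCL8 rose in both lines (2.55 and 2.86), in an NF-kB list with medians of 0.42 and 0.59 (camera adjusted p = 0.0612 and 0.0786). The MAPK phosphatases DUSP6 (-0.98 and -1.09) and DUSP4 (-0.65 and -0.49) fell, in a list with medians of -0.19 and -0.28 (0.130 and 0.0950). Without replicate 3 of both knockout lines the MAPK list was called in knockout 1 (median -0.30, camera adjusted p = 7.94e-04, and adjusted p = 0.0908 with an estimated correlation), and so was the retinoic acid list (0.0337, and adjusted p = 0.370 with an estimated correlation). Between the lines the mesenchymal (0.00648), bone metastasis (0.0143), TGF-beta (0.0349) and G2/M (0.00308) lists were then called as higher in knockout 2, with adjusted p = 0.140, 0.148, 0.197 and 0.298 with an estimated correlation.

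Mesenchymal, TGF-beta and YAP/TAZ genes moved both ways. The collagen VI genes COL6A1 (-1.63 and -1.38) and COL6A2 (-1.50 and -1.20) fell in both lines, as did ID2, a member of the TGF-beta list (-2.58 and -1.92). The ligand gene TGFB3 (1.47 and 1.67) and CYR61 (1.22 and 1.84) rose. In the TGF-beta list 3 rose and 3 fell in knockout 1 (median 0.15, mean -0.04, camera direction down, adjusted p = 0.951), and 7 rose and 6 fell in knockout 2 (median -0.17, mean 0.24, direction up, 0.498). In the YAP/TAZ list 6 rose and 1 fell in knockout 1 (median 0.20, 0.0850), and 7 rose and 3 fell in knockout 2 (median -0.04, mean 0.35, direction up, 0.229). The mesenchymal list had medians of 0.33 and 0.35 (0.654 and 0.328), with camera direction down in knockout 1, where the mean was 0.02. In the 2 lines the medians were 0.04 and -0.27 for hypoxia and glycolysis (0.643 and 0.653), 0.05 and 0.13 for cAMP response (0.327 and 0.283), -0.02 and -0.20 for STAT3 (0.643 and 0.498), 0.28 and -0.03 for EGFR ligands and receptors (0.289 and 0.328), and 0.38 and -0.19 for retinoic acid response (0.317 and 0.724). They were 0.10 and 0.19 for Wnt (0.860 and 0.604, with a mean of -0.15 in knockout 1), 0.11 and -0.04 for apoptosis regulators (0.287 and 0.661, with a mean of 0.10 in knockout 2), 0.06 and 0.00 for neuroendocrine markers (0.871 and 0.695), and -0.12 and 0.23 for haematopoietic and endothelial markers (0.654 and 0.526, with means of 0.01 and -0.55). In knockout 1 the Notch and fatty acid lists had medians of -0.08 and -0.12 (0.287 and 0.460). The hypoxia gene NDRG1 fell in both lines (-1.15 and -1.72) and the neuroendocrine marker SYT1 rose (1.19 and 1.39).

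Other splits of the 6 libraries into groups of 3 number 10 with the real one, too few for a share under 0.05. The real split had the highest count (1 of 10) for knockout 1 (2413 genes, highest other 0 in limma, or 765 unadjusted against 4264), knockout 2 (5781, highest other 0, or 413 against 6860) and the 2 lines (4173, highest other 0, or 1534 against 5610). Of the 10 splits of the 2 lines, 4 parted every same-number pair, where the highest other had 539 unadjusted, and the 6 that parted 1 pair reached 1534. For lists called by camera the real split gave 9 in knockout 1 and 17 in knockout 2, and the highest other 6 and 10. For genes called the same way in both lines, 1 of 100 splits, the real one, reached 1552, with 647 for the highest other. Splits that mix libraries of different lines widen the spread within groups, so this shows that libraries grouped by line. With 1 line per label it does not exclude chance differences between the lines. For the mean of both lines, fitted as 6 libraries against 3, 2 of 84 splits reached 1775, the real one and another. That other split called 3980 genes and set the 3 knockout 2 libraries against the rest, which points to a structure of the samples. The real grouping was therefore not the strongest, and its share does not exclude chance differences between the lines.

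The rise of cell division genes in both lines was weighed first. An exchange of the control and knockout 1 labels was argued against by GPRC5A, at -1.19 in knockout 1, if an edited gene gives no more transcript than an intact one. A rise carried by the third libraries alone was argued against by the G2/M median of 1.70 in the lower line without them. A culture state shared with the third libraries that also differs from the control cultures stays open. Genes low in the third library of 1 line were followed in libraries 1 and 2 of the other line. There 61.7% (94 genes) and 68.8% (189 genes) were lower than control. Among genes high in the third library the shares lower than control were 19.2% (120 genes) and 16.2% (228 genes). For all 9902 genes they were 50.1% and 51.6%. Both sets leaned the same way as in the third library, so such a state may contribute. Whether the knockouts had an effect of their own on these genes could not be told apart from it.

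The transcripts near 0 in both lines were weighed next, and 12 genes had at least 5 RPM in control and at most 3 reads in each knockout line, among them GABRA3, TLR4, CSMD2 and others named after their values were seen, and there were 2 genes with the reverse pattern. The 54 expressed neighbours within 500 kb had median log2 fold changes of -0.21 and -0.33, above the -0.5 set beforehand, but that bound was wrong for deletion around each gene, because 5 of the 12 genes had fewer than 3 neighbours (GABRA3 and TLR4 0, EMB 1) and 18 of the 54 belonged to CEACAM5. Gene by gene, deletion of the region was argued against for EBF2 (neighbour medians 0.27 and 0.52), NOS1 (-0.04 and -0.31) and, narrowly, CEACAM5 (-0.33, SE 0.169, and -0.23). It stays open for CST1 (-0.01 and -0.15, SE 0.456 in knockout 2), CSMD2 (0.08 and -0.60), GLB1L2 (-0.42 and -0.92), ESM1 (-1.03 and -0.82) and the genes with fewer neighbours. Smaller deletions, silencing and descent of the lines from cells that differed beforehand were not tested.

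Blocks of neighbouring genes that shifted together were weighed last. The filter on low values was argued against, since 64 windows lay beyond the limit with genes at 20 RPM or more, and so was GC content, since 57 of 77 windows stayed beyond it after its trend was removed. A chromosome copy number that differs between the knockout lines and the control cells is a candidate explanation, as a hypothesis from the same data. The 43 windows in knockout 2 would go with it. Of the 12 windows beyond the limit in both lines, 11 shifted the same way. There a difference in the lines cannot be told from a difference in the control cells. Windows beyond the limit held 23% of the called genes in knockout 1, against 10.3% of the tested genes, and 18.6% against 12.3% in knockout 2. The windows were picked by the fold changes that also gave the calls. An excess of called genes in them was thus built in and is no separate evidence for copy number. Outside these windows the G2/M medians were 2.31 and 2.87.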
